A study of Mus musculus with 2 samples.

How the data were processed

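Single-cell RNA sequencing was used to profile cells labelled as microglia-like and taken from the central nervous system of mice that had received haematopoietic stem and progenitor cells (HSPCs, the blood-forming cells of the bone marrow). Per the labels' protocols, GFP-positive and GFP-negative cells were sorted from the lineage-negative pool of Cx3cr1 heterozygous mice and injected into the veins of CD45.1 recipients conditioned with 4 doses of 25 mg/kg busulfan, a drug that empties the marrow niche. The same protocol text is given for both libraries. There were 2 libraries, 1 labelled Cx3cr1 heterozygous (replicate 1) and 1 labelled wild type (replicate 1). The labels used here give no sex, age, time after transplantation or number of animals.

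Libraries were made with the 10x Genomics Chromium 3′ kit (v3.1) and sequenced as paired-end reads, per the labels' protocols. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized. The authors used Cell Ranger 4.0 and the mm10 mouse genome, per the submitters' processing notes. Per the file headers, the matrices were written by Cell Ranger 5.0.0, and which version made the counts was not settled. The lowest UMI total of a listed barcode was 500 in both libraries. Of 32285 listed genes, 32235 had an identifier in the GENCODE M21 annotation (GRCm38), from which positions were taken.

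Cells were kept with at least 500 genes and under 10% mitochondrial UMIs. This kept 1489 of 1837 barcodes (81.1%) of the heterozygous library and 1949 of 2359 (82.6%) of the wild-type library. Scrublet, run in scanpy 1.11.5 at an expected rate of 0.008 per 1000 cells, called 0 doublets in either library. Its thresholds (0.0885 and 0.128) lay above the highest scores (0.0765 and 0.0756), so no cell was removed as a doublet. Both libraries were clustered together without integration, using counts scaled to 10000 per cell, log1p values, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 0.5 with seed 0. Clusters were named from fixed marker lists of 18 cell types. A name needed more markers of its type than of any other among the 10 leading genes, ranked by fold over the other cells after adding 10 CPM (counts scaled to the UMI total of the cells summed) among genes with at least 20 UMIs. It also needed at least 3 markers that were 1.5-fold higher and present in at least 10% of cells, no fewer than any other type had. That scoring rule was set after the data were seen, while the markers were fixed before. Of 15 clusters, 2 stayed unnamed.

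The main population held the microglia-like and monocyte-like clusters and unnamed clusters with C1qa or Csf1r at 500 CPM or more, 5 clusters in all. That level was also set after the data were seen. It left 1 unnamed cluster out, which held 5.84% of the heterozygous and 2.82% of the wild-type cells. UMIs were summed per library within the population, class or cluster and expressed as CPM of that sum. With 1 library per genotype no test across samples exists. Ratios carry exact conditional binomial intervals, CPM values exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and all covering counting error only. Ratios are the heterozygous over the wild-type library.

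Genes were named by a rule fixed before the data were examined. Cx3cr1 came first. Among genes with at least 50 UMIs over both libraries, a mean of at least 20 CPM and a ratio beyond 1.5-fold, the 12 highest and 12 lowest ratios followed, leaving out predicted, ribosomal, mitochondrial and sex-marker genes. For each of 21 fixed gene lists, up to 4 members with the highest absolute log2 ratio beyond 1.5-fold were added, or the most abundant members where none passed. Some genes that this rule takes are not reported here. Other genes named in a cluster or class were chosen after their values were seen. A list was described by its median log2 ratio, an interval from 500 Poisson draws, and its percentile among 10000 random lists of the same size matched in 20 expression bins. Members without a UMI in either of the libraries were left out of its median. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs. On simulated counts for the main population, the 95% intervals held the true log2 ratio for 95.2% of 9674 genes. These counts were Poisson draws, the model behind the intervals, so this checked the computation and not the spread among real cells.

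Alternatives fixed beforehand were no cell filter, a stricter filter (1000 genes, under 5% mitochondrial UMIs), doublets kept, TMM scaling (edgeR 4.0.16 in R 4.3.3), median-of-ratios scaling, equal weight per cell, all kept cells, microglia-like clusters only, proliferating clusters left out, thinning to 2000 or 1000 UMIs or none, minimums of 10 or 200 UMIs, resolutions of 1.0 and 0.25, and each library clustered alone. Added after seeing the data were: leaving out barcodes found in both libraries, giving each cluster the same share in both libraries, comparing Y-marked wild-type with Xist-marked heterozygous cells, leaving out cells over 30000 UMIs, and clustering without the named genes and sex markers. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.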

Results

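Microglia are the resident macrophages of the brain, and Cx3cr1 encodes the fractalkine receptor by which they sense a chemokine made by neurons. The series compared cells taken from the central nervous system after transplantation of HSPCs, in 1 library labelled Cx3cr1 heterozygous and 1 labelled wild type, asking how the transcriptional profile of their microglia-like progeny differed by donor genotype. The labels gave both libraries the same protocol with heterozygous donors, so which donor cells gave the wild-type library was not stated. The heterozygous library held 17828344 UMIs in 1837 barcodes and the wild-type library 22062823 UMIs in 2359 barcodes. Kept cells had a median of 6880 and 6637 UMIs and 2130 and 2067 genes, respectively. With 1 library per genotype, each difference below compares these libraries and has no replicate check.

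Monocyte-like cells were a smaller part of the heterozygous library and a macrophage cluster led by Gpnmb, Spp1 and Apoe a larger one. Clustered without the named genes and sex markers, microglia-like cells were 17.4% (15.5 to 19.4) of 1489 heterozygous and 19.4% (17.7 to 21.2) of 1949 wild-type cells. Monocyte-like cells were 19.7% (17.8 to 21.9) and 31.0% (28.9 to 33.1). The Gpnmb-Spp1-Apoe cluster held 160 heterozygous cells, 10.7% (9.22 to 12.4), and 59 wild-type cells, 3.03% (2.31 to 3.89). Neutrophil-like cells were 21.4% (19.3 to 23.5) and 23.4% (21.5 to 25.3), and dendritic cell-like cells 13.4% (11.7 to 15.3) and 13.2% (11.7 to 14.8). The sort that gave the cells can set these shares. With each library clustered alone, microglia-like shares were 4.84% and 16.2%. The heterozygous library then had 72 cells named microglia-like, beside unnamed clusters of 167 and 179 cells with C1qa at 4188 and 3103 CPM. An unnamed wild-type cluster of 257 cells had C1qa at 2773 CPM. Whether microglia-like cells of the joint clustering lay in these unnamed clusters was not tabulated, so naming may set those shares. The wild-type library alone formed no cluster led by Gpnmb, although its border-associated macrophage-like cluster of 54 cells held Spp1, Apoe and Ms4a7 among its leading genes. Clustered without the named genes, the Gpnmb-Spp1-Apoe cluster took the name border-associated macrophage-like, while in the main clustering it stayed unnamed.

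**Figure D1:**
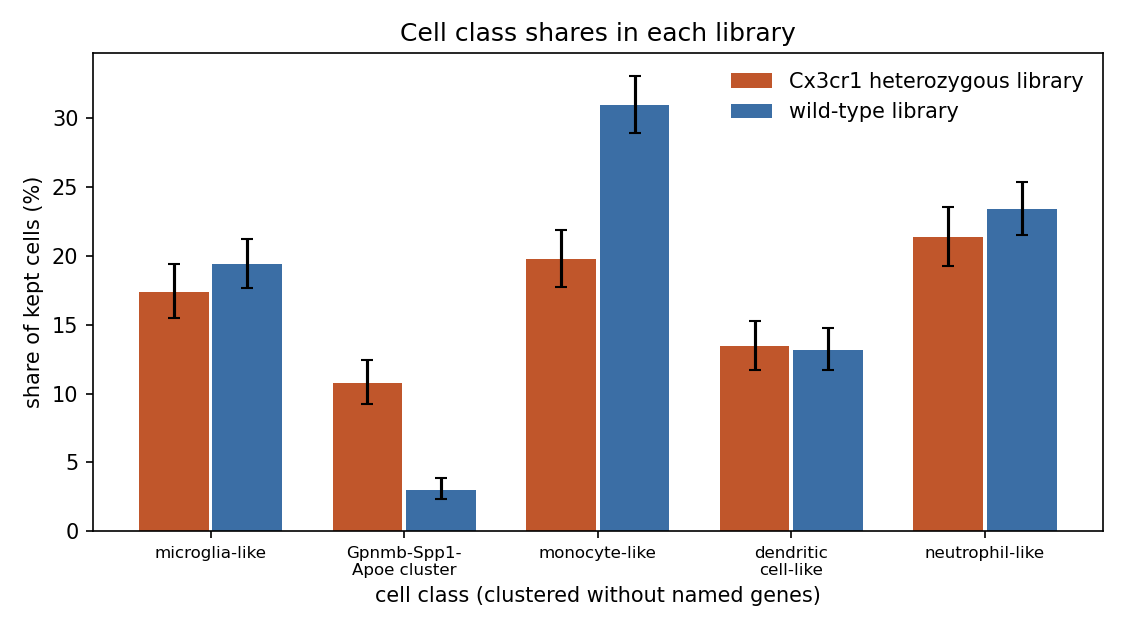
Share of kept cells (%, vertical axis) in 5 cell classes for the heterozygous and wild-type libraries, clustered without the named genes and sex markers. Error bars are Clopper-Pearson 95% intervals for counting error only, and the monocyte-like share was 19.7% against 31.0%.

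The microglia-like class joined a deep cluster whose 10 leading genes held P2ry12, Siglech, Olfml3 and Gpr34, genes of resident microglia, and a shallow cluster whose leading genes held Syngr1, Ltc4s, C1qb and Sparc. The leading genes of the deep cluster also held Cd209f, a gene of the border-associated macrophage list. At resolution 1.0 a border-associated macrophage-like cluster led by Cd209f, Cbr2 and Lyve1 stood apart, with 8 heterozygous and 12 wild-type cells. The monocyte-like class joined a cluster led by Vcan, Fn1, F13a1 and Ly6c2, the last a gene of classical monocytes, and a cluster whose leading genes held Cd300e, Ace and Treml4, genes of patrolling monocytes. In the main clustering the Ace-Treml4 cluster was 12.1% (10.5 to 13.9) of heterozygous and 21.0% (19.2 to 22.9) of wild-type cells. The classical cluster was 6.58% (5.38 to 7.96) and 8.52% (7.32 to 9.85). Smaller clusters were endothelial-like (5.31% and 1.80%), NK cell-like (2.15% and 3.03%), ependymal or choroid plexus-like (2.62% and 1.85%), B cell-like (0.873% and 0.410%) and mast cell or basophil-like (0.672% and 0.564%). Oligodendrocyte lineage-like cells were 11 of 1489 heterozygous and 0 of 1949 wild-type cells, which allows a share of up to 0.189%. Cell barcodes listed in both libraries made up 96.0% of the choroid plexus-like and 34.2% of the endothelial-like cells.

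The cells also differed in sex-linked transcripts. Xist, the transcript of the silenced X chromosome, stood at 729.98 CPM in the main population of the heterozygous library and 209 CPM in that of the wild-type library. The Y-linked Ddx3y stood at 0.473 and 69.5 CPM. Among cells with Xist or Y-linked UMIs but not both, Xist-marked cells were 97.9% (95.1 to 99.3) of heterozygous and 2.63% (1.21 to 4.94) of wild-type monocyte-like cells. In the microglia-like class they were 99.3% (96.2 to 99.98) and 70.4% (62.5 to 77.5). After thinning to 2000 UMIs the wild-type shares were 5.22% (2.13 to 10.5) and 83.3% (75.2 to 89.7). The wild-type share came from the deep microglia-like cluster, with 104 Xist-marked and 26 Y-marked cells, while the shallow one had 3 and 19, and 178 of its 200 cells had no mark. The heterozygous library had 122 and 1 in the deep and 22 and 0 in the shallow cluster. Both marks were held by 32 of the 181 wild-type and 1 of the 130 heterozygous cells of the deep cluster. Whether these were multiplets was not tested. The genotype label and the mix of sex marks therefore differed together in these comparisons of the libraries. In the deep microglia-like cluster, however, most marked cells of both libraries were Xist-marked.

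**Figure D2:**
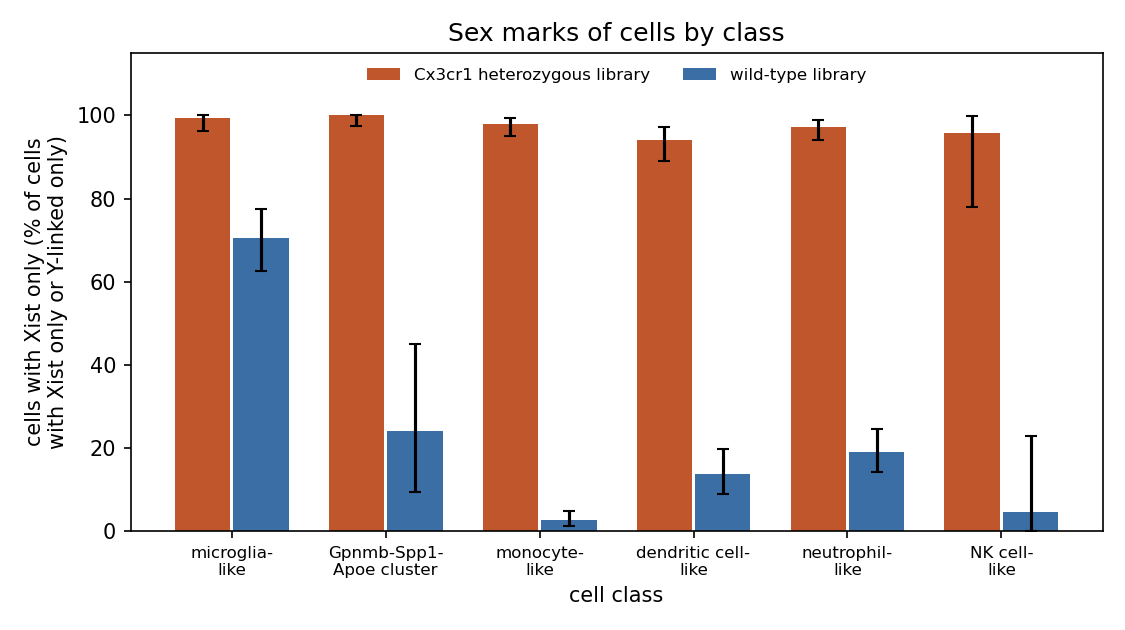
Cells with Xist and no Y-linked UMI, as a percent of cells carrying only one kind of mark (vertical axis), by cell class and library, with Clopper-Pearson 95% intervals for counting error only. In the wild-type library the share was 70.4% in microglia-like and 2.63% in monocyte-like cells.

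Cx3cr1 (ENSMUSG00000052336, protein coding, GRCm38 chromosome 9, 119901616 to 120069879, minus strand) stood at nearly the same level in both libraries over the main population and was lower in the heterozygous library within the monocyte-like class and the Gpnmb-Spp1-Apoe cluster. Cx3cr1 was also lower there, by less, in the microglia-like, neutrophil-like and dendritic cell-like classes. In the main population of 695 heterozygous and 1001 wild-type cells it reached 877 CPM (854 to 899.9) and 888 CPM (868 to 909), a ratio of 0.987 (0.953 to 1.02). In microglia-like cells it reached 1557 and 1734 CPM, a ratio of 0.898 (0.861 to 0.937), and in their shallow cluster the ratio was 1.11 (0.972 to 1.27). Set against the Y-marked wild-type cells alone, Xist-marked heterozygous microglia-like cells had a Cx3cr1 log2 ratio of 1.06 (0.92 to 1.20), a comparison added after seeing the data. That comparison also mixed the clusters differently, with 122 deep and 22 shallow heterozygous cells against 26 deep and 19 shallow wild-type ones. Over all their cells, Cx3cr1 reached 1891 and 2097 CPM in the deep cluster and 677 and 609 CPM in the shallow one. In monocyte-like cells it reached 211 and 319 CPM, a ratio of 0.663 (0.599 to 0.733). Of their clusters the Ace-Treml4 one had a ratio of 0.660 (0.586 to 0.741), while the classical one had 0.877 (0.715 to 1.07), an interval that includes 1. In the Gpnmb-Spp1-Apoe cluster it reached 919 and 1158 CPM, a ratio of 0.793 (0.707 to 0.892). In dendritic cell-like cells the ratio was 0.917 (0.842 to 0.999), and in neutrophil-like cells it was 0.825 (0.793 to 0.857). The neutrophil-like cells also carried microglial transcripts, with C1qa, C1qb and C1qc together at 5744 and 5472 CPM. Whether their Cx3cr1 UMIs came from neutrophils was not tested. The labels do not say which part of the gene is altered, so 3′ counts that lie outside it would not check the genotype.

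After thinning to 2000 UMIs, 59.8% (55.8 to 63.7) of 602 heterozygous and 58.0% (54.6 to 61.4) of 831 wild-type cells of the main population held a Cx3cr1 UMI. Thinning left out 93 heterozygous and 170 wild-type cells, and the unthinned shares were 78.4% and 76.5%. An Apoe UMI was held by 81.2% (77.9 to 84.3) and 64.5% (61.1 to 67.8), a Ms4a7 UMI by 33.6% (29.8 to 37.5) and 14.1% (11.8 to 16.6), and a Spp1 UMI by 15.9% (13.1 to 19.1) and 5.90% (4.39 to 7.72). The unthinned shares were 93.7% and 83.1% for Apoe, 42.7% and 22.6% for Ms4a7, and 25.2% and 11.99% for Spp1. All these shares mix cell classes. Thinned Ms4a7 shares were 33.3% and 26.5% in microglia-like cells and 3.66% and 0.794% in monocyte-like cells. For Apoe they were 93.3% and 85.0% in microglia-like and 61.8% and 49.4% in monocyte-like cells. For Cx3cr1 they were 76.2% and 78.4% in microglia-like and 36.6% and 44.2% in monocyte-like cells. In NK cell-like cells, which should lack Apoe and Ms4a7, thinned shares were 44.0% of 25 and 17.6% of 51 cells for Apoe. Spp1 was found in 2 of 25 and 6 of 51 of them, and Ms4a7 in 0 of 25 and 0 of 51, which allows up to 13.7% and 6.98%. Cx3cr1, which NK cells can express themselves, was found in 3 of 25 and 17 of 51. Median depths before thinning were 7715 and 6563 UMIs in the main population and 8347 and 5226 UMIs in the NK cell-like cells. The Spp1 share of the wild-type main population lay below its NK cell-like share of 11.8% (4.44 to 23.9). That NK cell-like share was 10.5% at 1000 UMIs and 13.6% unthinned. Whether these cells expressed Spp1 themselves was not tested, so it is no sure measure of background. Of 2137 wild-type Spp1 UMIs, 1307 lay in the Gpnmb-Spp1-Apoe cluster, at 4038 CPM.

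Gpnmb, Spp1, Igf1, Plau and Apoe had the highest ratios among the 12 genes named for high ratios. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a membrane glycoprotein of phagocytic macrophages, stood at 217 CPM in the heterozygous and 11.2 CPM in the wild-type library, a log2 ratio of 4.28 (3.96 to 4.60). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes the secreted protein osteopontin, stood at 1589 and 272 CPM, a log2 ratio of 2.55 (2.48 to 2.61). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), the lipid carrier apolipoprotein E, stood at 22725 and 7100.0 CPM, a log2 ratio of 1.68 (1.66 to 1.69). Ms4a7, a membrane protein of macrophages outside the microglial lineage, had a log2 ratio of 1.54 (1.44 to 1.64), and the growth factor gene Igf1 one of 1.78 (1.51 to 2.06). Plau (urokinase), Sash1, Mmp14 (a membrane-bound protease), Hebp1, Pld3, Cpq and Cd63 (a lysosomal tetraspanin) followed with log2 ratios of 1.69, 1.57, 1.47, 1.22, 1.19, 1.19 and 1.18. These values mix cell classes in different shares. The Gpnmb-Spp1-Apoe cluster held 99682 of the 144168 heterozygous Apoe UMIs and 19069 of the 55770 wild-type ones. Within it the log2 ratios were 2.38 (1.97 to 2.81) for Gpnmb, 0.51 (0.42 to 0.59) for Spp1, 0.24 (0.22 to 0.26) for Apoe and -0.01 (-0.16 to 0.15) for Ms4a7. With the same cluster shares in both libraries, 10 of the 24 named genes kept their direction beyond 1.5-fold.

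Within the microglia-like class, Gpnmb (82.7 against 9.43 CPM, log2 ratio 3.13) and Spp1 (742 against 239.7 CPM, 1.63) were higher in the heterozygous library. A Gpnmb UMI was held by few of these cells, 19 of 265 heterozygous and 12 of 381 wild-type ones, and after thinning by 13 of 210 and 4 of 287. In thinned NK cell-like cells it was found in 0 of 25 and 0 of 51. After thinning, a Spp1 UMI was held by 36 of 210 heterozygous and 20 of 287 wild-type microglia-like cells. The wild-type share, 6.97%, lay below that of the wild-type NK cell-like cells, 11.8%. Apoe, Ms4a7 and Plau were higher by log2 ratios of 0.65 (0.63 to 0.67), 0.61 (0.46 to 0.75) and 0.91 (0.46 to 1.36). For Xist-marked heterozygous over Y-marked wild-type microglia-like cells the log2 ratio was 0.02 (-0.01 to 0.06) for Apoe and -0.01 (-0.23 to 0.22) for Ms4a7. Igf1 had a log2 ratio of 0.35, with an interval from -0.06 to 0.75. In the monocyte-like class Spp1 had a log2 ratio of 0.16 (-0.28 to 0.59) and Apoe one of 0.18 (0.09 to 0.27). Xist was higher in heterozygous microglia-like cells by a log2 ratio of 0.75, and Ddx3y stood at 0.420 against 39.1 CPM.

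**Figure D3:**
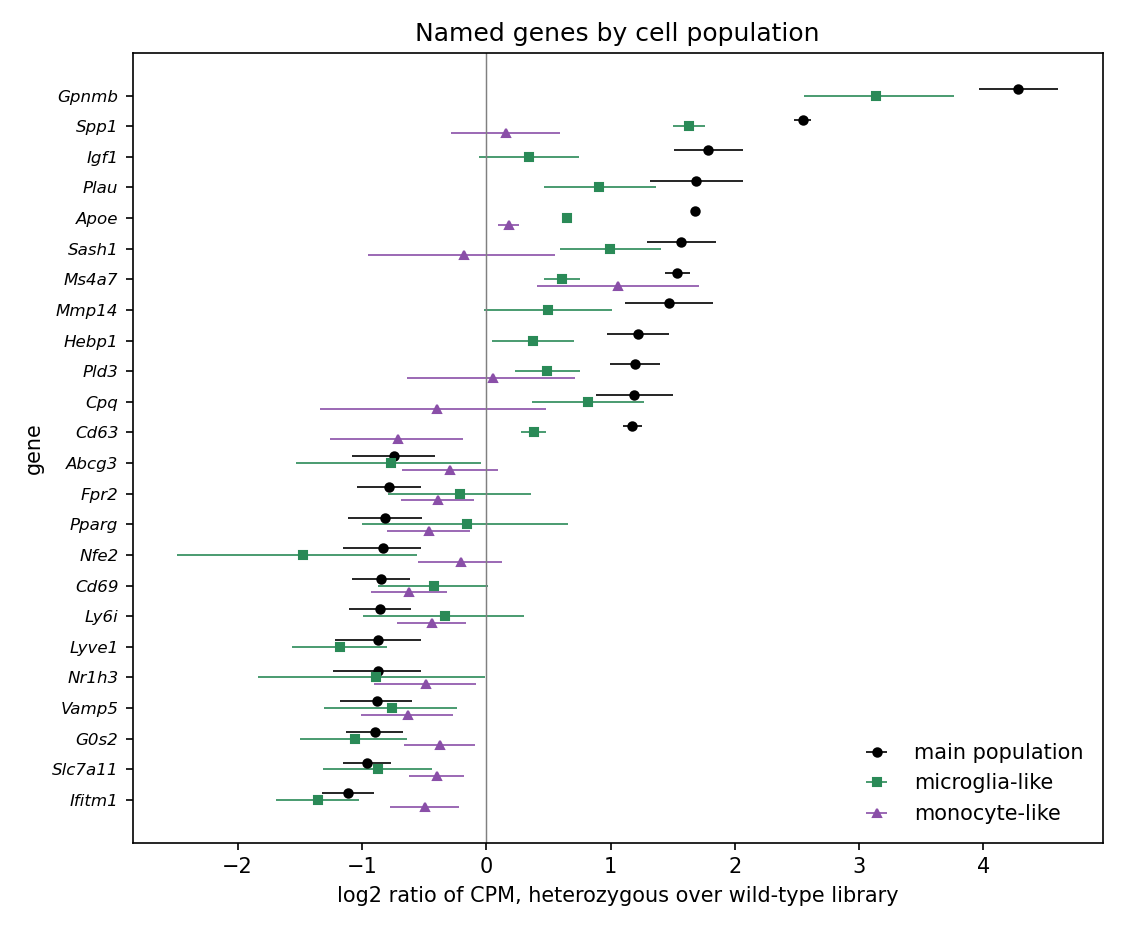
Log2 ratio of CPM, heterozygous over wild-type library (horizontal axis), of the 24 named genes in the main population, microglia-like and monocyte-like cells, with 95% counting intervals and points only where a gene had at least 50 UMIs. Gpnmb had the highest ratio, 4.28 in the main population and 3.13 in microglia-like cells.

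Of the 12 genes named for low ratios, Ifitm1 had the lowest. Ifitm1, an interferon-induced membrane protein, stood at 41.6 CPM in the heterozygous and 89.9 CPM in the wild-type library, a log2 ratio of -1.11 (-1.32 to -0.90). Slc7a11 (the cystine transporter), G0s2 (an inhibitor of fat breakdown) and Vamp5 had log2 ratios of -0.96, -0.90 and -0.88. Nr1h3 and Pparg, nuclear receptors of lipid metabolism, had log2 ratios of -0.87 and -0.81. Lyve1 (a receptor of perivascular macrophages), Ly6i, Cd69 (an activation marker), Nfe2, Fpr2 (a formyl peptide receptor) and Abcg3 had log2 ratios of -0.87, -0.85, -0.84, -0.83, -0.78 and -0.74. These values, too, mix cell classes in different shares. Monocyte-like cells held 266 of the 298 wild-type Pparg UMIs and 328 of the 393 wild-type Fpr2 UMIs. In microglia-like cells Ifitm1, G0s2 and Lyve1 were lower in the heterozygous library by log2 ratios of -1.35, -1.06 and -1.17. Pparg, Fpr2, Ly6i and Cd69 had ratios of -0.16, -0.21, -0.33 and -0.42 there, with intervals reaching both signs. In monocyte-like cells Ifitm1, Vamp5 and Cd69 were lower by -0.49, -0.63 and -0.62. Nfe2 (-0.21) and Abcg3 (-0.29) had intervals reaching both signs there. Ifitm1 and G0s2 were also among the 10 leading genes of a neutrophil-like cluster, and the neutrophil genes S100a8 and S100a9 together stood at 2327 and 3362 CPM in the microglia-like cells. Lyve1 was a leading gene of the small border-associated macrophage-like cluster found at resolution 1.0. Whether cells of that cluster lay in the microglia-like class was not tabulated. Lyve1 in monocyte-like cells went the other way, with 16 against 7 UMIs. Over all kept cells Cd69 turned to a log2 ratio of 0.08. Between Xist-marked heterozygous and Y-marked wild-type cells Lyve1 turned to 2.86 in the main population and to 1.70 in the microglia-like class. Of the main-population cells so compared, 229 of 520 heterozygous and 333 of 397 wild-type cells were monocyte-like.

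Genes of the disease-associated microglia list, which mark phagocytic microglia around damage, had a higher median in the heterozygous library in the main population, the deep microglia-like cluster and the Gpnmb-Spp1-Apoe cluster. In the main population 14 of 26 measured members were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.64 (0.44 to 0.70) at percentile 100 of random lists. Ch25h, a cholesterol hydroxylase, had a log2 ratio of 2.09 beside Gpnmb, Spp1 and Igf1. In microglia-like cells the median was 0.21 (0.12 to 0.25), at percentile 100, and 3 of 25 members passed 1.5-fold. Its deep cluster had a median of 0.31 (0.23 to 0.40), at percentile 100, and its shallow cluster one of -0.13 (-0.19 to -0.03), at percentile 4.12. In the Gpnmb-Spp1-Apoe cluster it was 0.43 (0.34 to 0.49), at percentile 100, with the fatty-acid binding protein Fabp5 at 2.31 and the galectin Lgals3 at 1.37. In monocyte-like cells it was -0.06, at percentile 2.24. The cells of the Gpnmb-Spp1-Apoe cluster were Xist-marked in 147 of 147 heterozygous and 6 of 25 wild-type marked cells. Its 10 leading genes held Gpnmb, Spp1, Apoe, Igf1 and Ctsd of the disease-associated list, and 152 of its 197 cells were heterozygous. The list's median within it was not computed for the clustering without the named genes. The median of 0.43 there is therefore no independent support.

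Lysosomal genes also had a higher median in the main population. It was 0.33 (0.30 to 0.37) over 41 members in the main population, at percentile 100, with 7 members at least 1.5-fold higher, among them the protease Ctsd (0.93) and the cholesterol transporter Npc1 (0.73), and also Galc (0.91) and Mcoln1 (0.76). The median was 0.07 in microglia-like cells (0.13 in the deep and -0.16 in the shallow cluster) and 0.25 in the Gpnmb-Spp1-Apoe cluster. Lipid and cholesterol genes had a median of 0.18 (-0.01 to 0.26) at percentile 99.9 in the main population, with the cholesterol exporter Abca1 at 1.02 and the sterol synthesis enzyme Sqle at -1.06. Over all kept cells that median turned to -0.05. Both lists overlap the disease-associated list, the lysosomal one in Cd68, Ctsb, Ctsd, Ctsl and Ctsz and the lipid one in Apoe, Ch25h, Fabp5 and Lpl.

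Few genes of homeostatic microglia passed 1.5-fold, and their median had opposite signs in the main population and the microglia-like class. The median over 25 members was 0.18 (0.11 to 0.20), at percentile 100, in the main population, where Fcrls (0.67) and Rnase4 (0.66) passed 1.5-fold. In microglia-like cells it was -0.11 (-0.16 to -0.08), at percentile 0.055, with the purinergic receptor P2ry12 at -0.31, the lectin Siglech at -0.51 and the transcription factor Sall1 at -0.46. In the deep cluster that median was -0.05 (-0.11 to -0.02), at percentile 16.3, and in the shallow one -0.21 (-0.31 to -0.15), at percentile 0.055. Over the class, none of the 25 passed 1.5-fold. For Xist-marked heterozygous over Y-marked wild-type microglia-like cells these turned to 1.59 for P2ry12, 0.88 for Siglech and 2.42 for Sall1. TGF-beta and microglia transcription factors had medians of 0.09 (0.04 to 0.19) in the main population and -0.03 in microglia-like cells, with Cebpb at -0.41, Spi1 at -0.29 and Mef2c at 0.23 in the main population. With the same cluster shares in both libraries the main population's medians turned to -0.11 for homeostatic microglia and -0.02 for these factors.

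Border-associated macrophage genes, which mark macrophages of the meninges and vessel walls, split in direction. In the main population 7 of 18 were at least 1.5-fold higher and 4 lower, with a median of 0.22 (0.10 to 0.50) at percentile 99.9. The chemokine Ccl24 (1.92) was higher, and the lectin Cd209f (-1.93) and the haemoglobin scavenger receptor Cd163 (-1.53) were lower. In monocyte-like cells the median was 0.65 (0.40 to 1.01), at percentile 100, with the mannose receptor Mrc1 at 1.83 and Dab2 at 1.92, and in microglia-like cells it was -0.08 (-0.15 in the deep and 0.34 in the shallow cluster). With shared barcodes left out the main population's median turned to -0.12. The bone-marrow-derived brain macrophage list had a median of -0.05 at percentile 62.3, with Axl at 1.02 and Cd38 at 0.68.

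Monocyte genes had a median in the main population of -0.36 (-0.40 to -0.33) at percentile 0, with the peptidase Ace at -0.62, and 0.13 within monocyte-like cells, where Fn1 (0.77) and Vcan (0.72) were higher. Adhesion and chemokine receptors had a median of -0.18 (-0.22 to -0.08) at percentile 0.2, although S1pr1 (1.06) and Itga6 (0.75) were higher. With the same cluster shares in both libraries these medians turned to 0.05 and 0.02. Interferon response genes had a median of -0.16 (-0.26 to -0.08) at percentile 0.18, with Bst2 at 1.05 and Ddx58 at -0.67, and the median was -0.16 in monocyte-like and 0.11 in microglia-like cells. MHC class II genes had medians of -0.10 in the main population and -0.25 (-0.42 to -0.14) in microglia-like cells, where H2-Eb1 (-0.86) and H2-Aa (-0.68) were lower. The class II median was -1.36 (-1.55 to -1.14) in the shallow microglia-like cluster, with 5 of 6 members lower, and 0.13 (-0.04 to 0.54) in the deep one. Marked cells of the shallow cluster were Xist-marked in 22 of 22 heterozygous and 3 of 22 wild-type cells.

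Inflammatory cytokine genes had a lower median in the heterozygous cells of the Gpnmb-Spp1-Apoe cluster and a higher one in those of the shallow microglia-like cluster. In the Gpnmb-Spp1-Apoe cluster the median was -0.49 (-0.60 to -0.29), at percentile 0, with 7 of 20 members at least 1.5-fold lower in the heterozygous library. The interleukins Il1a (-2.03) and Il1b (-1.65), the chemokine Ccl4 (-1.50) and the prostaglandin synthase Ptgs2 (-3.33) were lower. In the shallow microglia-like cluster it was 0.54 (0.36 to 0.69), at percentile 100, with 8 of 18 members higher, and in the deep one -0.06. Immediate early and heat shock genes had a median of -0.26 in the Gpnmb-Spp1-Apoe cluster and -0.14 in microglia-like cells, both at percentile 0, but the shallow microglia-like cluster had 0.31 (0.17 to 0.43), at percentile 99.97, and the deep one -0.11. The main population's medians were -0.06 and -0.08, with Cxcl16 at 1.06 and Fos at 0.03. The Gpnmb-Spp1-Apoe cluster rested on 45 wild-type cells, and 19 of them were Y-marked.

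**Figure D4:**
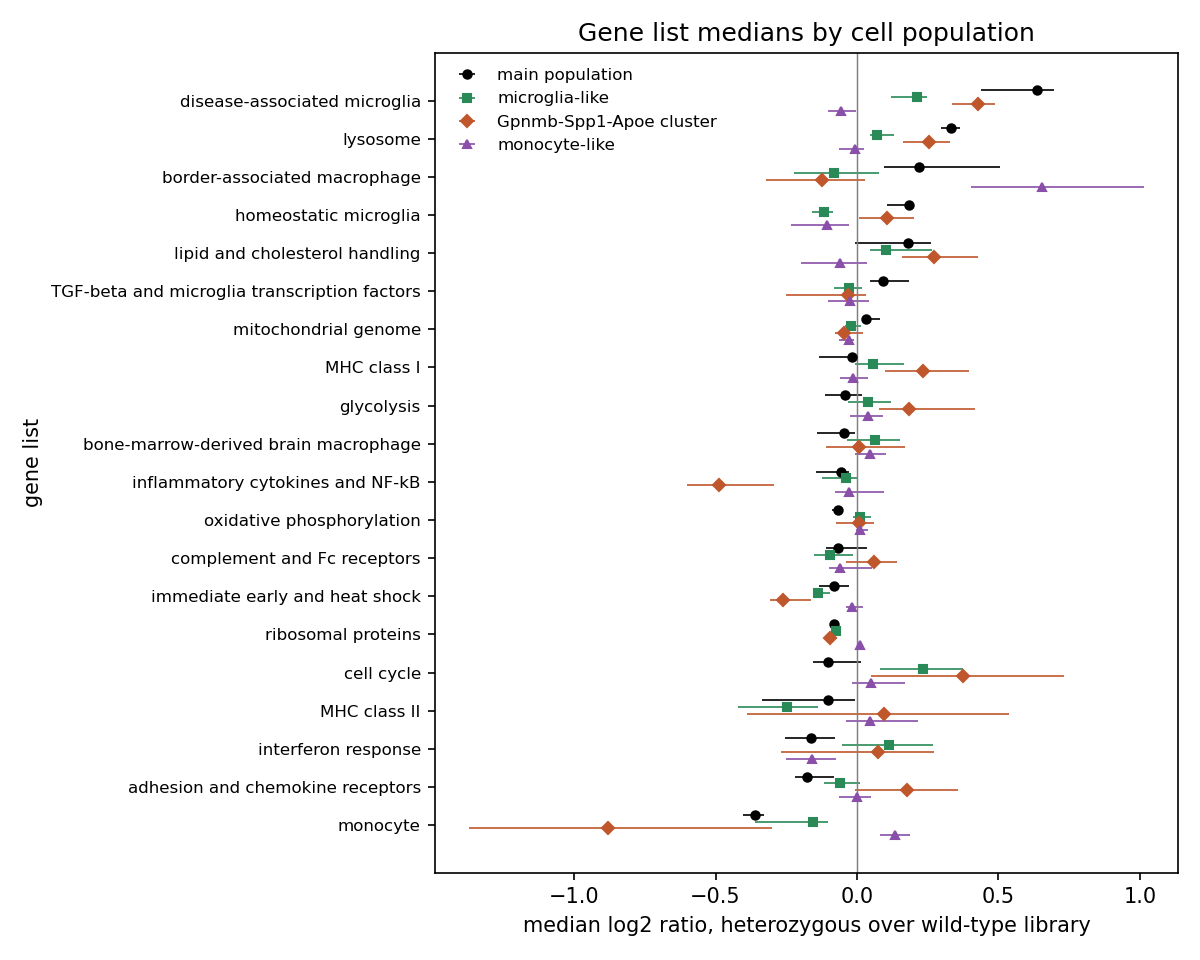
Median log2 ratio, heterozygous over wild-type library (horizontal axis), of 20 gene lists in the main population, microglia-like cells, the Gpnmb-Spp1-Apoe cluster and monocyte-like cells, with 95% intervals from Poisson draws. The disease-associated list had medians of 0.64, 0.21, 0.43 and -0.06, in that order.

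The other lists had medians near 0 in the main population. They were -0.02 for MHC class I (B2m -0.02, H2-D1 0.02), -0.07 for complement and Fc receptors (C3ar1 0.75, C4b -0.89), -0.10 for cell cycle genes (Hmgb2 -0.16, Tubb5 -0.17) and -0.04 for glycolysis (Gapdh -0.07, Pkm -0.08). Oxidative phosphorylation, ribosomal protein and mitochondrial genome lists had medians of -0.07, -0.08 and 0.03, with Cox6a2 at 1.13, Rpl3l at -0.86 and mt-Co3 at 0.03. Cell cycle genes had a median of 0.23 in microglia-like cells but -0.43 (-0.60 to -0.32) in their deep cluster, with 8 of 20 members lower, and 0.97 (0.76 to 1.17) in their shallow cluster, with 12 of 16 members higher. Over all kept cells it was 0.19, at percentile 100. The X and Y markers had a median of -5.84.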

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

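Of the tests in this part, those of chance barcode reuse, of reads carried over between libraries, of free RNA, of barcodes carried over into the wild-type microglia-like cells, of heterozygous donor cells in the wild-type sort and of the deep microglia-like cluster alone were chosen after related values had been seen.

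A signal in data outside the comparisons was that 339 cell barcodes were listed in both libraries. Their UMI totals fell in 4 bands: 35 had a median of 64.3 times more UMIs in the heterozygous library, 27 a median of 66.9 times more in the wild-type library, and 172 and 105 had similar totals, with median ratios of 1.43 and 0.920. Of 178 pairs with both entries kept, 89.9% (84.5 to 93.9) fell in the same cluster, against 15.3% by chance, which argues against chance reuse for these pairs. Reads carried over between libraries may account for them, since they would put both entries in the same cluster. Which libraries the reads of the similar-total bands came from stays open, and no biological explanation was tested.

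Clusters named neutrophil-like held 792 kept cells in a sort described as microglia-like, and they carried microglial transcripts, with C1qa, C1qb and C1qc together at 5588 CPM beside S100a8 and S100a9. Free RNA is argued against, since the NK cell-like cluster held 3.86% of that C1q level. Multiplets of a neutrophil and a microglial cell may account for part of it: at 5000 UMIs per cell, 12.6% (8.48 to 17.8) of wild-type neutrophil-like cells with at least 1000 CPM of C1q held both Xist and Y-linked UMIs, against 1.52% (0.184 to 5.37) of those with less, a difference of 11.1 percentage points that argues against single cells with both gene sets as the whole cause. Scrublet called none of these cells, and whether part of them are single cells with both gene sets stays open. Genotype was not tested as a cause, since both libraries showed the pattern, with 61.5% and 60.6% of neutrophil-like cells above that C1q level.

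In the wild-type library, 107 microglia-like cells carried Xist and no Y-linked UMI, while 2.63% of its marked monocyte-like cells were Xist-marked. Barcodes carried over from the other library are argued against, since 3.74% (1.03 to 9.30) of these cells sat at shared barcodes. Heterozygous donor cells in the wild-type sort are argued against too, as the whole source. Of Xist-marked cells of the microglia-like and Gpnmb-Spp1-Apoe clusters, 5.31% (1.97 to 11.2) fell in the latter, against 50.5% (44.6 to 56.4) in the heterozygous library. The heterozygous share may itself mix donor and recipient cells, so a smaller part from such donor cells stays open. Resident recipient microglia may be the source of the Xist-marked wild-type cells: Sall1 was 13.7 times (6.46 to 34.7) as high in Xist-marked as in Y-marked cells of the microglia-like and Gpnmb-Spp1-Apoe clusters, and Ms4a7 0.554 times (0.472 to 0.649). In the deep microglia-like cluster alone, with 104 and 26 such cells, the ratios were 11.3 (4.72 to 35.3) and 0.474 (0.384 to 0.585). The deep cluster held another 32 wild-type cells with both marks, so part of its Y-marked cells may be multiplets, which was not tested. In the heterozygous library nearly all marked cells were Xist-marked, so these marks could not part donor from recipient cells there.

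Other cell types appeared outside the main population. Ependymal or choroid plexus-like clusters held 75 kept cells, NK cell-like clusters 91 and oligodendrocyte lineage-like clusters 11. Of these, 96.0%, 13.2% and 0% sat at barcodes listed in both libraries, so the first may largely be carried-over reads.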

How the results depend on the processing

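No paired analysis was possible because each genotype had 1 library. Keeping doublets and leaving out proliferating clusters changed no cell, so these settings tested nothing. TMM and median-of-ratios scaling shifted log2 ratios by -0.03 and -0.04 and turned no named gene. Turns of lists are given for lists outside the middle 95% of random lists in the main population, and neither scaling turned one of these. Both scalings turned the mitochondrial genome list, at percentile 94.8, from 0.03 to -0.00222 and -0.00616. The settings with shared barcodes left out, the same cluster shares, sex-marked cells, cells over 30000 UMIs left out and clustering without the named genes were chosen after seeing the data. Where no cause is given, the cause was not tested.

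The Cx3cr1 log2 ratio, -0.02 in the main population, was 0.12 with cells weighted equally, -0.20 over all kept cells, -0.15 in microglia-like clusters only, 0.16 with cells thinned to 2000 UMIs, -0.21 with the same cluster shares and 1.18 for Y-marked wild-type against Xist-marked heterozygous cells. That last comparison also mixed classes differently: 333 of its 397 wild-type but 229 of its 520 heterozygous cells were monocyte-like. Cx3cr1 reached 211 (heterozygous) and 319 CPM (wild type) in all monocyte-like cells, against 1557 and 1734 CPM in microglia-like cells. Of the 24 named genes, 15 kept their direction beyond 1.5-fold in microglia-like clusters only and 10 with the same cluster shares. Lists below the 2.5 percentile numbered 4 in the main population, 8 over all kept cells and 7 with the same cluster shares. Without a cell filter Cd69 turned to 0.38 and the lipid list to -0.0038, and over all kept cells to 0.0777 and -0.0456. In microglia-like clusters only, list medians turned to -0.11 (homeostatic), -0.0816 (border-associated), 0.11 (interferon), -0.0279 (TGF-beta) and 0.31 (X and Y markers). Lists inside that range turned there too, to 0.23 (cell cycle), 0.0643 (bone-marrow-derived), 0.0581 (MHC class I), 0.0402 (glycolysis), 0.0112 (oxidative phosphorylation) and -0.0208 (mitochondrial genome). With shared barcodes left out they turned to -0.12 (border-associated) and 1.60 (X and Y markers). Members at 0 in a library were left out of medians, and Y-linked genes were near 0 in the heterozygous library (Ddx3y 0.473 CPM in the main population). The turns of the X and Y markers can therefore come from dropped Y-linked members. With the same cluster shares list medians turned to -0.11 (homeostatic), -0.0859 (border-associated), 0.0500 (monocyte), 0.0171 (adhesion) and -0.0202 (TGF-beta). That setting also weighted clusters by their cells, while the main values summed UMIs, so these turns cannot be put down to the cluster shares alone. Lyve1 turned to 2.86 for sex-marked cells, whose mix of classes also differed. The cell cycle list, -0.10 in the main population, also turned to 0.24 without a cell filter, 0.20 under the stricter filter, 0.10 with cells weighted equally, 0.19 over all kept cells, 0.11 with thinned cells, 0.0922 with shared barcodes left out, 0.23 with the same cluster shares and 0.14 with cells over 30000 UMIs left out. Other lists inside that range changed sign under further settings.

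Class shares moved with the clustering, heterozygous before wild type. At resolution 1.0 they were 14.0% and 15.4% (microglia-like), 21.0% and 34.1% (monocyte-like), 15.9% and 17.3% (neutrophil-like) and 4.30% and 4.87% (dendritic cell-like). At resolution 0.25 they were 8.80% and 10.1% (microglia-like), 14.6% and 24.8% (monocyte-like) and 19.0% and 11.7% (Gpnmb-Spp1-Apoe), and 12.2% for wild-type dendritic cell-like cells. Under the stricter filter they were 13.1% and 16.1%, 21.3% and 32.7%, 17.8% and 16.3%, and 5.13% and 5.73% for the same 4 classes as at resolution 1.0, and 14.1% for the heterozygous Gpnmb-Spp1-Apoe cluster. With each library clustered alone, microglia-like shares were 4.84% and 16.2%, Gpnmb-Spp1-Apoe shares 11.95% and 0%, heterozygous monocyte-like and dendritic cell-like shares 22.03% and 0%, and the wild-type neutrophil-like share 14.8%. With shared barcodes left out, monocyte-like shares were 22.4% and 36.1%, Gpnmb-Spp1-Apoe shares 13.8% and 3.66%, the heterozygous neutrophil-like share 24.5% and the wild-type dendritic cell-like share 10.7%. With cells over 30000 UMIs left out, neutrophil-like shares were 14.1% and 17.4%, Gpnmb-Spp1-Apoe shares 12.5% and 3.49%, the heterozygous dendritic cell-like share 17.0% and the wild-type microglia-like share 21.5%. Shares of 0% came from naming: clustered alone, the heterozygous cluster with H2-Eb1 and Cd209a stayed unnamed, and no wild-type cluster had both Gpnmb and Spp1 among its 10 leading genes. Naming may also set the heterozygous microglia-like share of 4.84%, since an unnamed cluster of 167 cells had C1qa at 4188 CPM. At resolution 0.25 the Gpnmb-Spp1-Apoe cluster held 512 cells and had all 13 microglia markers raised. Its share and the microglia-like share there therefore do not cover the same cells as in the main clustering. Class shares were not computed without a cell filter, where Gpnmb and Spp1 led a microglia-like cluster.

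Shares of cells with a Cx3cr1 UMI were 44.3% and 43.6% at 1000 UMIs and 78.4% and 76.5% unthinned. Median UMIs were 5003 and 5103 without a cell filter.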

Other observations

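The genes named here and the comparisons of sex-marked cells were chosen after seeing the data. Dendritic cell-like cells differed between the libraries in macrophage and monocyte genes. Border-associated macrophage genes had a median log2 ratio of 0.78 there, at percentile 100 of random lists, with the chemokine Ccl8 at 3.88, Cbr2 at 1.71 and the scavenger receptor Stab1 at 1.13, while Ccl24 stood at -5.36. Monocyte genes had a median of -0.44, at percentile 0, with Ace at -1.38, Treml4 at -1.26 and Plac8 at -0.82, although Fn1 stood at 1.29. This class was not uniform: it had C1qa at 2549 CPM, and at resolution 1.0 dendritic cell-like cells were 4.30% of heterozygous and 4.87% of wild-type cells, with C1qa at 317 CPM. An unnamed cluster led by H2-Eb1 then held 245 cells of both libraries, with C1qa at 4379 CPM. The ratios were not computed for these parts apart. In neutrophil-like cells the median over all measured genes was -0.09, and monocyte genes (-0.37) and ribosomal protein genes (-0.24) lay at percentile 0. MHC class II genes had a median of -0.46 there, with H2-Eb1 at -0.57 and H2-Aa at -0.48. Interferon response genes had a median of -0.26 there, with Irf7 at -0.67 and Isg15 at -0.62. Part of these neutrophil-like cells carried microglial transcripts, with C1qa, C1qb and C1qc together at 5744 and 5472 CPM. Marked dendritic cell-like cells were Xist-marked in 94.1% of the heterozygous and 13.7% of the wild-type library, and after thinning to 2000 UMIs in 92 of 92 and 21 of 70 cells.

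In the deep microglia-like cluster of the wild-type library, 26 Y-marked cells had 2.18 times the Apoe level of 104 Xist-marked ones, 4.46 times that of the oxidase subunit Cybb, 3.67 times that of the lectin Clec12a and 2.59 times that of the lysozyme Lyz2. The Xist-marked cells had 6.79 times the P2ry12 level, 3.98 times that of Tmem119, 5.93 times that of Siglech and 3.14 times that of Cx3cr1. Another 32 of the 181 wild-type cells of this cluster held both marks and were in neither group. Whether part of the Y-marked cells were multiplets was not tested. Among microglia-like cells, the log2 ratio of 144 Xist-marked heterozygous over 45 Y-marked wild-type cells (122 deep and 22 shallow against 26 deep and 19 shallow ones) was 4.49 for Gpnmb (156 against 2 UMIs), 2.26 for Spp1, 0.02 for Apoe and -0.01 for Ms4a7. It was 1.06 for Cx3cr1, 1.59 for P2ry12, 1.14 for Tmem119, 2.42 for Sall1, 0.88 for Siglech and 1.70 for Lyve1, each opposite in sign to the ratio over the whole microglia-like class. The ratios between the libraries therefore mix sex mark, library and cluster.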
